A study of Homo sapiens with 2 samples.

How the data were processed

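FANCD2-bound DNA was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 293T cells, an established human embryonic kidney line. The 2 samples comprise 1 library from cells without UV and 1 from cells harvested 3 hours after UV. The labels write the dose as 30 J and give no area. Nuclei were sonicated and the DNA was recovered with an antibody against FANCD2, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.7, HOMER, and the builds hg19 and mm9, without saying which step used which. Positions below are given as hg19, as deposited. The mouse build was set aside because the chromosome names are human, and GRCh38 because the last regions of chromosome 1 lie beyond its last gene in that build.

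The authors called regions in each library separately with the findPeaks program of HOMER in its factor style, against an input library of the same condition, per the file headers. They required at least 2-fold more tags than input, a Poisson p-value over input of 1e-04 or less and a false discovery rate of 0.001. The filter on local signal and the filter on clonal tags were switched off in the command that the headers record. Tags at the same position were capped before calling, per the file headers, at 1 tag per bp without UV and at 2 tags per bp after UV. Each region has the same length within a list, centred on its highest pile-up.

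Each deposited list gives 7 values per region. The deposited normalized tag count is a signal scaled to 10000000 tags per library, duplicates included. The deposited score is, from its whole-number values and its minimum, the number of tags in the region after the cap. A signal of tags scaled to the input library, the input tags, their ratio as a fold over input, and a Poisson p-value complete the authors' test against input. The focus ratio is a fraction that the authors' program gives for how tags of the 2 strands lie around the centre. The deposited input tags had a floor, at 5.2 tags without UV and 7.2 after UV. The floor was 2.00 and 2.01 times the mean input expected over the length of a region, and input below it cannot be read. The length over which input tags were counted was not examined. If it was 2 times that of a region, the floor is about the mean input. Folds and scores are the authors' values throughout. They are ranked within a list, and where both lists' values stand side by side the caps, minimums and floors behind them differ.

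From these files the enrichment of a region was computed as its score over the expected tags per region in the header, with an exact Poisson 95% interval. The number of tags after the cap was the header's tags per bp times its genome size. The lists were compared by overlap of at least 1 bp with bedtools 2.31.1. Chance overlap came from 1000 random placements of each no-UV region between the first and last UV region of its chromosome. The smallest p that these placements can give is 0.001. UV regions were counted in 1 Mb windows between the first and last region of each chromosome, and windows with at least 3 times the median were called dense. Dense windows at most 1 window apart formed a domain if it was at least 3 Mb long. For each chromosome the position of 1 step in density was found by Poisson likelihood, with at least 20 Mb on each side. Input in dense windows was compared with that elsewhere by a Mantel-Haenszel odds ratio over strata of scaled tags, since the authors' input filter depends on them. Shares carry exact Clopper-Pearson 95% intervals. All intervals cover counting error only, since PCR reads are not independent molecules and neighbouring regions are not independent. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. On simulated lists of the real sizes with 60 planted overlaps among 257 regions, the overlap above chance came to 58.8. With 100 of 3003 simulated windows raised from a Poisson mean of 10 to a mean of 60, all 100 were found and no others. The real windows were more spread, with 10th and 90th percentiles of 2 and 26 regions. This simulation therefore does not test the minimum of 30 on the real counts. In 50 simulated chromosomes of 120 windows, the step was placed within 5 windows in 50.

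There was 1 library per condition, so no test between the conditions was made, and tests describe the deposited lists. Before the data were examined, the overlap comparison, score and fold minimums, merging of nearby regions, and the rule for named items were fixed. That rule named the 10 regions of highest score per list and the 10 shared regions of highest UV score. It also named TP63, FANCD2 and members of preset gene lists (Fanconi anaemia, repair and checkpoint genes, histones, ribosomal proteins, fragile site genes and others). No annotation of hg19 was used here, the lists carry no gene names, and positions were not carried between builds. Genes, promoter shares, distances to transcription start sites and the gene lists were therefore not analysed here, nor were the preset alternatives that need them. The windows, domains and steps, and the pairing of chromosomes 1 and 13, were chosen after the data were seen.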

Results

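The series asked where FANCD2, a DNA repair protein that acts with the Fanconi anaemia proteins at damaged DNA, bound the genome of 293T cells after UV. Immunoprecipitated DNA was sequenced from 1 library without UV and 1 library after UV, and a list of called regions represents each. The library without UV held 33301307 tags and the UV library 46061052. After the authors' cap on tags at one position, 2532000 and 19212000 tags remained, or 7.60% and 41.7% of the total. The cap was 1 tag per bp without UV and 2 tags per bp after UV, so these numbers are not like for like. With no replicates, every difference between the lists compares these libraries and has no replicate check.

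The first comparison was the number and strength of FANCD2 regions with and without UV. The list after UV held 42034 regions and the list without UV held 257, a ratio of 164. Regions covered 3.40% of tags after UV and 0.09% without UV, which the authors' headers give as the approximate efficiency of the immunoprecipitation. The UV regions were found on all 24 chromosomes, and the no-UV regions on 23, with none of the 257 on chromosome 20. That count of 0 has an exact upper limit of 1.43%. The UV library held 1.38 times as many tags in total, and 7.59 times as many after the unequal caps.

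The median score, which counts tags after the cap, was 14 after UV, where the minimum was 12, and 7 without UV, where it was 7. Normalized tags and folds both include duplicates. The median region had 7.8 normalized tags per 10000000 after UV (quartiles 7.2 and 8.7) and 28.5 without UV (quartiles 24.3 and 34.5). The median fold over input was 3.25 after UV (quartiles 3.06 and 3.71) and 13.7 without UV (quartiles 6.37 and 16.7). Input was above its floor at 3.27% of UV regions and 34.2% of no-UV regions, so most of these folds are tags over the floor. A median no-UV region held 12.8 tags for each tag left after the cap (quartiles 11.0 and 14.8), and a median UV region held 2.65 (quartiles 2.43 and 2.92). In the UV list 15808 regions, 37.6%, sat exactly at the minimum score of 12, and 214 regions, 0.51%, reached at least 2 times that minimum. The minimum score of 7 without UV held 172 of 257 regions, or 66.9%. The 2 minimums came from the same false discovery rate of 0.001 but were not equal in enrichment. A score of 12 was 5.34 times the expected tags per region after UV, whereas 7 was 30.6 times the expected tags without UV. Only 1 UV region reached 30.6-fold enrichment. All 257 no-UV regions did so by construction, since this was the minimum of their own list. The expected tags rest on unequal caps, so the enrichments of the 2 lists are not like for like.

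**Figure D1:**
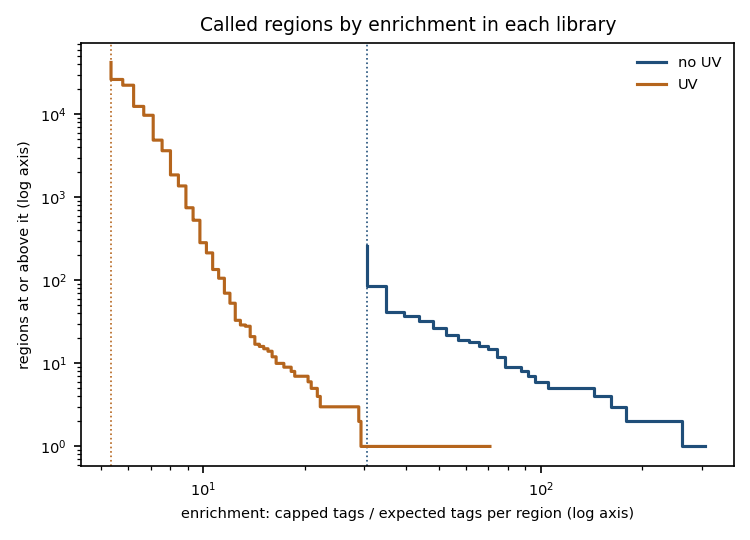
Number of called regions (vertical log axis) at or above each enrichment, the capped tags of a region over the expected tags per region (horizontal log axis), for the library without UV (blue) and after UV (brown); dotted lines mark each library's minimum. The UV list starts at 5.34-fold and the no-UV list at 30.6-fold, where 1 UV region remains.

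By score, the strongest region was the same in both lists. On chromosome 12 it spanned 102589763 to 102589997 after UV, with a score of 159 and 42.1-fold over input. Without UV it spanned 102589798 to 102589978, with a score of 70 and 199.64-fold over input, and input was at the floor in both lists. On chromosome 11, the UV list had a region at 5246992 to 5247226 with a score of 65 and another at 5246183 to 5246417 with a score of 49. The no-UV list had 5246268 to 5246448 there, with a score of 24, and input was again at the floor. On chromosome X, a region starting at 77359503 after UV scored 50 and its partner starting at 77359401 without UV scored 41. Input was above the floor there, at 30 tags in the UV condition and 24 tags without UV.

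The other leading UV regions were on chromosome 21 (starts 10702686 and 10702059, scores 66 and 47), chromosome 16 (33974585, score 46) and chromosome 2 (133020004, score 42). Chromosome 9 (68416904, score 41) and chromosome 13 (62349752, score 39) completed the 10 highest. Without UV the remaining leaders were on chromosome 21 (9827075, score 60), chromosome 1 (91852883, score 37) and chromosome 12 (20704337, score 33). Chromosome 15 (68132383, score 22), chromosome 19 (27734682 and 27737424, scores 21 and 20) and chromosome 2 (133012581, score 18) followed. Input tags were above the floor in 6 of the 10 leading UV regions and in 8 of the 10 leading no-UV regions. The deepest input, 360 tags, lay under the no-UV region on chromosome 21, which was 5.64-fold over it. Folds over input ran from 2.08 to 4.4 at those 6 UV regions and from 2.24 to 23.85 at those 8 no-UV regions. Repeats and mappability were not examined, so a high score there cannot be read as a FANCD2 site from the call alone.

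The second comparison set the positions called after UV against those called without UV. Of the 257 no-UV regions, 15 overlapped a UV region, or 5.84% (95% interval 3.30 to 9.44). Permuting the positions within each chromosome gave 2.16 overlaps on average and at most 8, so the overlap was 6.95 times chance (one-sided permutation test, p = 0.001, the smallest the placements can give). Shifts of at most 1 Mb, which keep the local density of regions, gave 5.41 on average and at most 14, and left the overlap at 2.77 times chance (permutation p = 0.001). Without a partner were 42019 UV regions and 242 no-UV regions.

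The scores of the 15 shared regions ran from 159 after UV and 70 without UV on chromosome 12 to 12 and 7 on chromosomes 1 and X, under caps of 2 tags per bp and 1 tag per bp. By score, all 15 were higher after UV. Relative to the expected tags per region, 2.25 after UV and 0.229 without UV, all 15 were instead higher without UV. The direction therefore rests on the expected tags, which come from unequal caps. Outside chromosome 12 the minimums fixed the order by enrichment, since a call without UV needed 30.6-fold. Only 1 UV region in the whole list, the one on chromosome 12, reached it. At the chromosome 12 region the enrichment was 306-fold without UV (238 to 386) and 70.7-fold after UV (60.2 to 82.6). At the chromosome X region it was 179-fold (128 to 243) and 22.2-fold (16.5 to 29.3), and at the chromosome 11 region 105-fold (67.1 to 156) and 21.8-fold (16.1 to 28.8). A shared region of chromosome 15 starting at 68132339 in the UV list had 96.1-fold (60.2 to 145) without UV and 13.8-fold (9.37 to 19.6) after UV. A second region on chromosome 11, starting at 11268133, had 74.2-fold (43.2 to 119) and 10.7-fold (6.84 to 15.9). The next were on chromosome 13 (62937595 and 68547873), chromosome 1 (34713044), chromosome 7 (157254059) and chromosome 15 (86440065), with 7.56- to 11.6-fold after UV and 30.6- to 48.0-fold without UV.

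**Figure D2:**
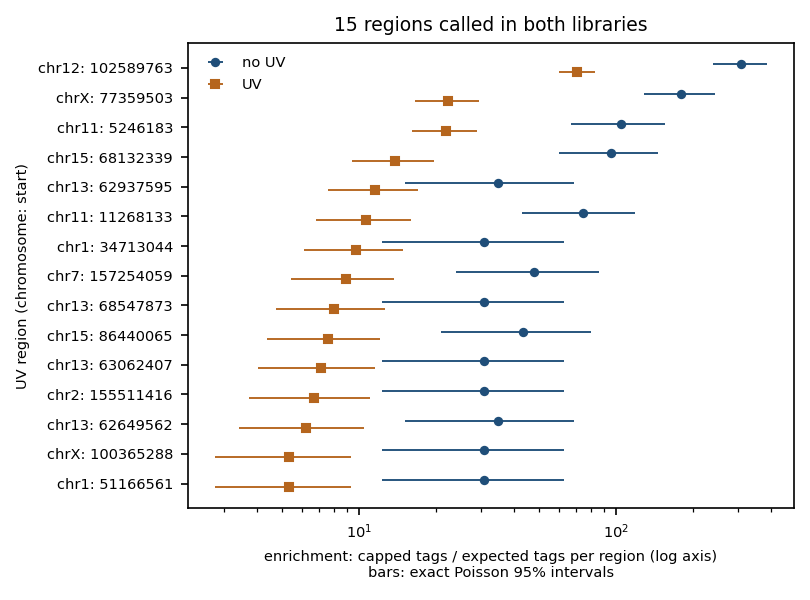
Enrichment over expected tags (horizontal log axis) of the 15 regions called in both libraries, without UV (blue circles) and after UV (brown squares), with exact Poisson 95% intervals as bars. The no-UV values start at the 30.6-fold minimum for a call, which 1 UV region, on chromosome 12, reached, so the minimums fixed the order of the libraries at the others.

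The third comparison was where along the genome the regions lay. Chromosome 13 held 4632 UV regions, 11.0% of the list (10.7 to 11.3), at 49.0 regions per Mb between its first and last region. Chromosome 1 held 6691, or 15.9% (15.6 to 16.3), at 27.0 per Mb. The mean over all chromosomes was 14.1 per Mb. Chromosome 19, the most gene-dense human chromosome, held 316 UV regions at 5.42 per Mb, the lowest density among the autosomes, followed by chromosome 16 at 6.62 per Mb. In the no-UV list, chromosome 13 held 43 regions, or 16.7% (12.4 to 21.9), and chromosome 1 held 39, or 15.2% (11.0 to 20.2). Together chromosomes 1 and 13, a pair chosen for these shares after the data were seen, held 26.9% of UV regions (26.5 to 27.4) and 31.9% of no-UV regions (26.3 to 38.0), in 11.5% of the length spanned. Of the 10 regions on chromosome Y after UV, 7 had input above the floor, and so did the 1 region there without UV.

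A part of the UV regions lay in broad domains of high density. The median 1 Mb window held 10 UV regions, the 10th and 90th percentiles were 2 and 26, and the fullest window held 353. The 219 windows with at least 30 regions made up 7.29% of the 3003 windows and held 12772 UV regions, 30.4% (29.9 to 30.8). These windows were chosen on the same counts, so a share above 7.29% was fixed by construction. The largest domain ran from 62 to 96 Mb on chromosome 13 and held 4209 UV regions at 124 per Mb (120 to 128). Within it the first 7 Mb held 278 regions per Mb (266 to 290) and the remaining 27 Mb held 83.9 per Mb (80.4 to 87.4). Chromosome 1 had domains at 220 to 246 Mb (65.5 per Mb) and at 55 to 79 Mb (54.0 per Mb). Chromosome 18 had one at 27 to 39 Mb (56.6 per Mb), chromosome 6 at 123 to 144 Mb (36.7 per Mb) and chromosome X at 100 to 112 Mb (34.7 per Mb). In all, 19 domains held 11082 of the 42034 UV regions.

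Of the 257 no-UV regions, 162 lay outside the dense windows and 95 fell in the dense windows defined on the UV list, or 37.0% (31.0 to 43.2), 5.07 times the share of windows that were dense. Without chromosome 13, 53 of 214 did, or 24.8% (19.1 to 31.1), in 6.36% of windows. The chromosome 13 domain held 42 no-UV regions. Its first 7 Mb held 3.57 per Mb (2.31 to 5.27) and its remaining 27 Mb held 0.63 per Mb (0.37 to 1.01), so the intervals of the 2 parts did not meet in either list.

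A single step in density was fitted to each chromosome, without a test against no step or a gradual change. On chromosome 13 the fitted density went from 8.35 to 80.6 UV regions per Mb at 62 Mb, and on chromosome 15 from 2.88 to 22.3 at 65 Mb. On chromosome 18 it went from 23.1 to 2.59 per Mb at 39 Mb. It went from 2.61 to 11.5 at 36 Mb of chromosome 8, from 13.3 to 3.80 at 177 Mb of chromosome 3, and from 9.42 to 27.0 at 133 Mb of chromosome 7. The 2 sides differed at least 2-fold on 11 of the 22 chromosomes examined. On 10 of those 11 the no-UV regions were also denser on the same side (two-sided exact sign test, p = 0.012). Some of these rested on few regions. The denser side held 6 against 5.07 expected from length on chromosome 4, 5 against 4.53 on chromosome 8 and 3 against 2.24 on chromosome X. The largest excess was on chromosome 13, with 42 against 23.7. Over all 21 chromosomes with a no-UV comparison, 12 had the same side (exact sign test, p = 0.66). Chromosome 3 was the exception among the larger steps, with 7 of its 8 no-UV regions on the side that holds most of its length.

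**Figure D3:**
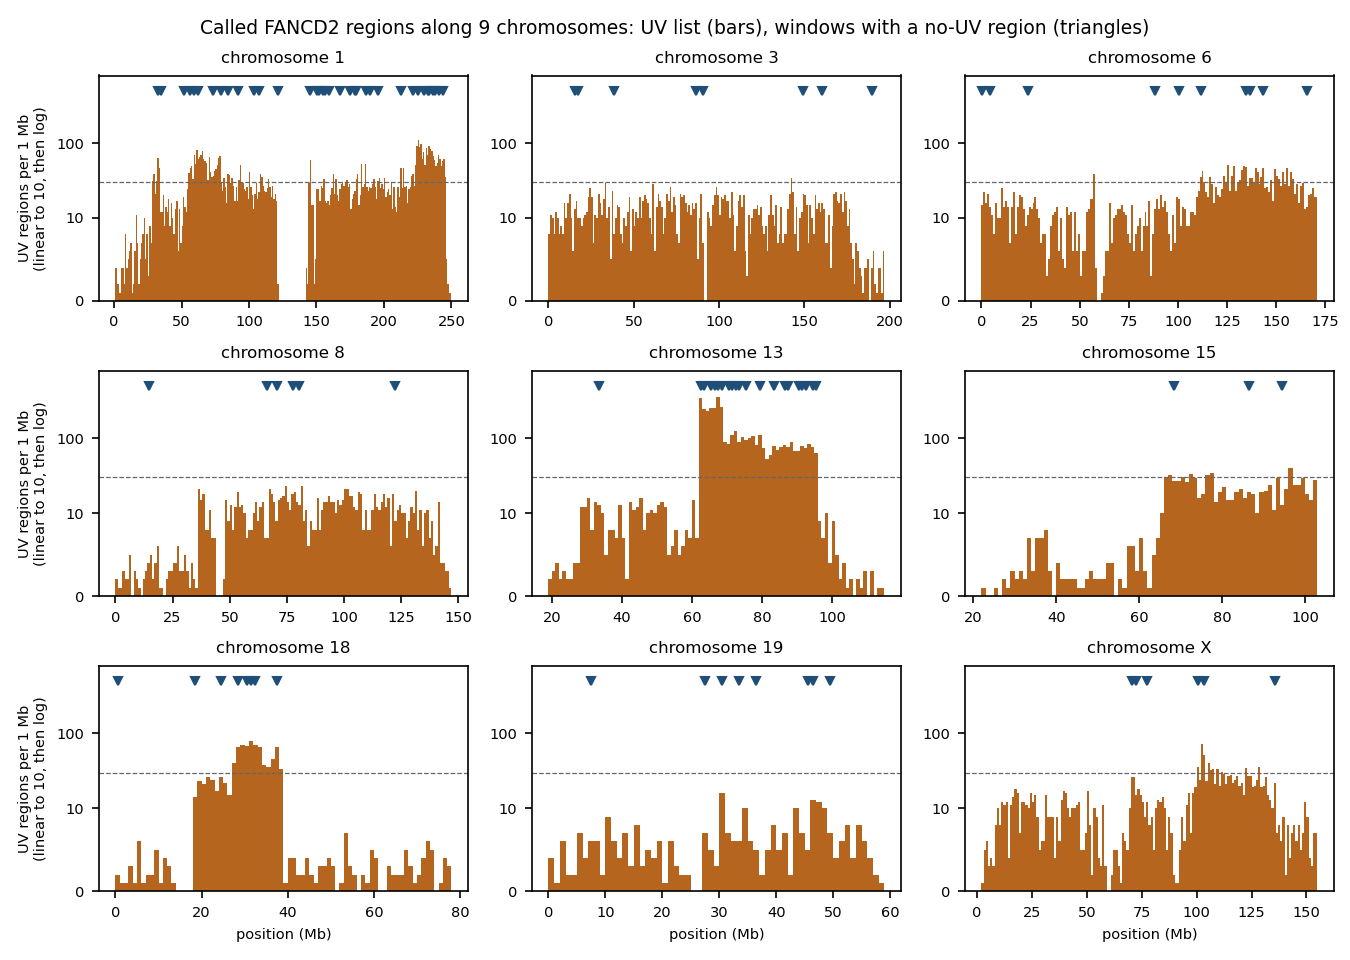
UV regions per 1 Mb window (bars, axis linear to 10 and logarithmic above) along 9 chromosomes against position in Mb; blue triangles mark windows with a no-UV region and the dashed line the minimum of 30 for a dense window. The 62 to 96 Mb domain of chromosome 13 holds 4209 UV and 42 no-UV regions.

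UV regions of higher score were more often in dense windows, which were defined on the counts of these same regions. The trend is therefore not independent of that definition. The share was 36.2% (35.6 to 36.9) of the 22357 UV regions with a score of at least 14, 63.6% (61.0 to 66.2) of the 1370 with at least 20, and 69.6% (63.0 to 75.7) of the 214 with at least 24. The median score was 14 in dense windows and 13 elsewhere, and the median fold over input was 3.34 and 3.25. Input tags were above the floor in 4.89% of UV regions in dense windows (4.53 to 5.28) and in 2.56% of those elsewhere (2.38 to 2.75).

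The median focus ratio was 0.953 without UV and 0.842 after UV.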

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

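All tests in this part were chosen after the result was seen. Input tags, which are not the main measurement, were above their floor at 88 of the 257 no-UV regions (34.2%, 28.5 to 40.4) and at 1375 UV regions (3.27%, 3.10 to 3.45). A value above the floor exceeds the limit that a count of 0 allows. How far it exceeds the mean input depends on the length over which input was counted, which was not examined.

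The first pattern is the small number of regions without UV. One candidate explanation is fewer tags after the cap in that library. Each capped tag of the UV regions was kept with the 13.2% chance that matches the no-UV density. Then 85.8 UV regions (SD 9.02) would be expected to reach 7 tags. This is fewer than the 257 called without UV. It is more than the 15 of those that overlapped a UV region, the count at the same positions. The caps differ, at 1 and 2 tags per bp. A UV cap of 1 would give 36.0 if it divided both density and scores by 2, and 2652 if it divided the density alone by 2. The test stays undecided, because the thinned scores had to reach 12 to be listed and the input filter was not applied after thinning. Whether UV raised FANCD2 occupancy at the called regions cannot be told apart from fewer tags after the cap. Only 1 UV region had the 30.6-fold enrichment a call without UV needed, and the other 42033 lay below it.

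The second pattern is the crowding of UV regions into dense windows. UV-dependent FANCD2 occupancy of these windows as its whole cause is argued against by the list without UV, in which 37.0% of regions lay in the same windows against 7.29% of windows (24.8% against 6.36% without chromosome 13). Higher DNA copy number is a candidate explanation, since this line is aneuploid: at matched tags, input was above the floor more often in the dense windows of chromosomes 1 and 13 (Mantel-Haenszel odds ratio 1.82, 1.61 to 2.06) and of the other chromosomes together (1.45, 1.22 to 1.72) than elsewhere. On each of the other chromosomes tested singly the interval included 1, with 1.05 (0.73 to 1.51) on chromosome 6, 1.15 (0.70 to 1.88) on chromosome 10, 0.94 (0.58 to 1.51) on chromosome 18 and 1.20 (0.67 to 2.14) on chromosome X. The no-UV list went the other way and keeps this explanation open, with unmatched odds ratios of 0.33 for chromosomes 1 and 13 (two-sided Fisher's exact test, p = 0.0013) and 0.26 for the others (p = 0.0074). This direction rested on regions of high input: 50 of the 53 no-UV regions with input over 3 times the floor lay outside dense windows. Among regions with input at most 3 times the floor, the unmatched odds ratio for all dense windows was 0.90 without UV and 1.99 after UV. That limit selects regions by the input being compared, so it does not settle the explanation. FANCD2 occupancy of these domains that does not depend on UV was not tested and stays open.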

How the results depend on the processing

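Equal minimum enrichment, input at the floor, local shifts, the pair of chromosomes 1 and 13 and all settings of the window analysis were added after seeing the data. With the minimum enrichment of the no-UV list applied to both lists, all 257 no-UV regions stayed by construction and 1 UV region stood against them. The ratio of 0.0039 turned the direction, and the alternative's own construction, the higher minimum, shows the cause. A score of at least 14 in both lists left 22357 UV and 19 no-UV regions (ratio 1177), and at least 4-fold over input left 5179 and 210 (ratio 24.7). With input at the floor, 169 no-UV regions remained, and the ratio was 241. Merging regions within 1 kb gave 40514 and 252, and no region lay on random, unplaced or mitochondrial sequences, so that setting moved nothing. Shared regions numbered 41 with centres within 1 kb and 11 with 50% reciprocal overlap, with no chance level computed for either. A distance of 1 kb is looser than an overlap, so the 41 cannot be read as an excess. Overlaps numbered 13 in UV regions scoring at least the median (chance 1.265) and 9 with input at the floor (chance 1.43). With as many UV as no-UV regions there were 6 (chance 0.029). The share of UV regions in dense windows was 48.1% at 2 times and 19.1% at 5 times the median, 24.9% with 5 Mb windows, 22.9% without chromosome 13, 29.9% with input at the floor and 36.2% for scores of at least the median. For no-UV regions it was 45.9%, 27.6%, 31.1%, 24.8% and 45.6% under the first 5 of these. Every no-UV share exceeded the share of windows that were dense under its setting (2.96% to 17.7%). The UV shares did so by construction, since the dense windows were defined on the UV regions. Chromosomes 1 and 13 held 31.7% of UV regions scoring at least the median. Except where a setting's construction shows it, the cause was not tested. Alternatives on promoters, gene lists and promoter scores were not run, because no hg19 annotation was used here. No paired analysis was possible because each condition had 1 library. Depth after the cap was 2532000 tags without UV, and whether it set the number called there was not decided.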

Other observations

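The tests in this part were chosen after the data were seen. A run of dense windows of 2 Mb, too short to count as a domain, lay at 81 to 83 Mb of chromosome 9. It held 277 UV regions (139 per Mb) and 6 no-UV regions. Its density was above that of every domain of at least 3 Mb, including the one of chromosome 13 taken whole. Another 2 Mb run, at 53 to 55 Mb of chromosome 10, held 137 UV regions and 1 no-UV region. Among smaller domains of at least 3 Mb, chromosome 9 at 18 to 22 Mb held 139 UV and 2 no-UV regions, and chromosome 17 at 55 to 60 Mb held 162 and 1. Chromosome 6 at 147 to 159 Mb held 406 UV regions and no no-UV region.

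Some no-UV regions gathered where UV regions were not dense. Outside the dense windows, 4 windows held 3 or more no-UV regions each, 18 in all, and input was above its floor at all 18. They were at 92 Mb of chromosome 2 (5 no-UV and 1 UV region), 42 Mb of chromosome 10 (3 and 5), 18 Mb of chromosome 18 (5 and 14) and 27 Mb of chromosome 19 (5 and 7). Median input there ran from 22 tags to 69 tags, against a floor of 5.2 tags without UV, with median folds of 2.32 to 3.13. Each of these windows lay next to a window with no called region in either list. Repeats and mappability were not examined here, so these regions cannot be read as FANCD2 sites from the calls alone.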
